A study of Rattus norvegicus with 6 samples.

How the data were processed

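Bulk RNA sequencing was done on 6 libraries from calvarial bone defects, holes made in the roof of the skull, of male Sprague-Dawley rats, an outbred albino stock. The defects had been filled with a hydrogel called CGG in the labels (3 libraries) or with a hydrogel called CGG-Cit (3 libraries), which the labels do not spell out. At week 4 after surgery the defect tissue was cut out and minced, and its RNA was isolated and sequenced in read pairs on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles and treatment labels. No label states that the libraries of a group come from separate rats, so p-values measure only the spread between these libraries, which may be technical.

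The deposited table gives FPKM (fragments per kilobase of gene, scaled by library size) for 34045 genes, 22250 of them protein coding and 1162 without a name. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build mRatBN7.2, with no role or order, and the annotation release and the strand setting are not given in the sources used here. The gene lengths in the deposited table, multiplied with FPKM, gave whole multiples of the value of 1 read in 100% of the values above 0 of every library, within 0.01 reads. The recovered totals were 14744207 to 16224920 assigned fragments per library, so 1 fragment in a gene of 1 kb was worth 0.0596 to 0.0657 FPKM. The library sizes behind this scaling lay within 1.99% of median-of-ratios size factors times the geometric mean total, so the table's scaling was close to such factors and not to the plain totals. The table's gene coordinates could not be tied to a build: the last gene on chromosome 1 ends at 282724300, beyond the last gene end of 270492571 in the GRCr8 gene table used here for symbols and synonyms. Coordinates are therefore printed as the table lists them, with no build. Without a strand setting, a gene and an overlapping or antisense neighbour cannot be told apart, and genes with near-identical copies (the alpha globins Hba-a1 and Hba-a2, C4b, the RT1 genes) are uncertain.

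Expression was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), without a block, for the 15965 genes with a mean of at least 0.5 FPKM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene passed at an adjusted p under 0.05. Every log2 fold change is CGG-Cit minus CGG on the log2(FPKM + 1) scale, which understates the change of low genes. Means are linear FPKM ± SD. The tests, 33 gene lists and the naming rule were fixed before the data were examined. The lists cover bone, stromal, immune, blood, vessel, muscle, fat, nerve, meningeal and skin cells, metabolism, chromatin enzymes, signalling, the cell cycle and stress. Of their 586 symbols 569 matched the table, 6 of them through a synonym, and the others were not analysed here. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with p adjusted over the 33 lists. It was tested again with an estimated correlation and with fry, which asks whether the genes of a list move 1 way without comparing them with other genes. A list score is the mean over the members of log2(FPKM + 1) centred on the 6 libraries.

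Named genes were the 10 largest rises and the 10 largest falls among named protein-coding genes that passed and whose groups did not overlap, up to 4 members of each list with the smallest p, and 18 genes fixed by name. The rule gave 158 measured genes, of which 114 passed. Genes outside that rule were chosen after their values were seen: Mmp9, Idh1, Slc2a1, Pfkfb4, Lef1 and the genes of the first 2 paragraphs under other observations, apart from Ccl3, Ccl9, Ccl19, Ccr7, Cxcl12, Col1a1 and Cox6a2, which the rule had named. Cxcl2, fixed by name, lay under the filter on low values, with 0.056 to 1.59 FPKM, and was not tested. Ep300, a histone acetyltransferase gene also fixed by name, was not tested under that symbol either, so 16 of the 18 were measured. Tables were prepared with Python 3.11.15 and pandas 2.3.3.

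The alternatives were 2 other pseudocounts (0.1 and 0.5), no filter and a mean of at least 2 FPKM, 4 other scalings (median-of-ratios factors, TPM, quantile normalization, equal totals without the 50 most abundant genes), robust variance estimation, sample quality weights, the replicate number as a block, each library left out in turn, and other thresholds. A fit with limma's voom on the recovered whole reads was chosen after seeing the data. Explanations weighed in the closing part used tests chosen after the results were seen, apart from the counts over the 10 splits of the 6 libraries into 3 and 3. A check for an exchanged library had been tried for the muscle genes and was replaced by the test of scaling, because such an exchange could not produce the pattern. A further test of the osteoblast genes is not reported here. A set of 15 marrow precursor genes was picked from the fixed lists after their values were seen, so its fall cannot exclude the explanation it was set against. Separate tests of its 5 B cell precursor genes and of a part of the osteocyte list were dropped, because these had been picked after their values were seen. The fit was tested on simulated libraries of 15921 genes, most of them unchanged: 39 of 99 genes with a true log2 change of 1 were called, 81 of 100 with a true change of 2, and 9 of 15722 unchanged genes. The simulated genes varied independently and few were changed, whereas 17.5% of the real genes passed, so these shares need not hold for the real libraries.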

Results

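Gene expression was measured by RNA sequencing in rat calvarial bone defects 4 weeks after surgery, in 3 libraries from defects filled with the CGG hydrogel and 3 from defects filled with the CGG-Cit hydrogel. The series title describes hydrogels that carry a metabolite of the tricarboxylic acid (TCA) cycle and ties them to neutrophils, recruitment of mesenchymal stromal cells and histone acetylation in bone formation. The comparison of CGG-Cit with CGG asks how the defect tissue responds to the 2 gels. Depth was even: the whole reads recovered from the FPKM table summed to 15054925, 16224920 and 15283405 in the CGG libraries and to 14744207, 15001310 and 16127352 in the CGG-Cit libraries. Across genes, log2 values correlated at 0.971 to 0.972 between CGG libraries, at 0.959 to 0.97 between CGG-Cit libraries and at 0.908 to 0.95 between the groups. CGG-Cit 3 was the CGG-Cit library closest to CGG, with correlations of 0.937 to 0.95.

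In the CGG-Cit defects 15 of 17 skeletal muscle genes, 17 of 18 neutrophil genes, 14 of 15 erythroid genes and 10 of 11 platelet genes were lower, as were 7 of 16 B and plasma cell genes and 7 of 21 osteoblast genes. Higher were 13 of 17 macrophage genes, 7 of 14 genes of antigen presentation and dendritic cells and 8 of 17 connective tissue genes. These 9 lists passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.425 to 0.585), and the osteoblast list did not pass fry (0.0886). Ckm, the muscle creatine kinase, averaged 1231 ± 233.6 FPKM in CGG (SD, n = 3) and 20.62 ± 23.6 in CGG-Cit, and S100a8, a neutrophil calcium-binding protein, 5432 ± 356.3 and 1287 ± 563.4. Bglap, which encodes osteocalcin, averaged 3006 ± 360.7 and 1237 ± 542 FPKM, while Cd68, a macrophage lysosomal protein, averaged 217.6 ± 27.28 and 531.1 ± 140.1. Of 15965 genes tested, 1237 were higher and 1561 lower in CGG-Cit with limma at an adjusted p under 0.05, 44.2% of the calls being higher. The change was at least 2-fold on the log scale for 328 of the higher and 672 of the lower genes. The groups did not overlap in 41.7% of the genes, where chance gives 10%.

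The split of these calls depended on scaling: after rescaling to TPM, which moved the median of all genes from 0.002 to 0.16, 2203 genes were higher and 948 lower, 69.9% higher. The counts fell when a library was left out, to 536 higher and 666 lower without CGG 1, 420 and 498 without CGG 2, 122 and 190 without CGG 3, 515 and 488 without CGG-Cit 1 and 149 and 249 without CGG-Cit 2. They stood at 1312 and 1622 without CGG-Cit 3. All genes called both in these fits and in the fit of all 6 libraries had the same direction. In the fits without a library this was fixed in advance, as the groups overlapped in 0 of the called genes. Of the 114 named genes that passed, 39 no longer did without CGG 1, 60 without CGG 2, 81 without CGG 3, 48 without CGG-Cit 1, 74 without CGG-Cit 2 and 5 without CGG-Cit 3, and 27 passed in all 18 alternative fits. Without the filter on low values, with 22222 genes tested, 18 of the named genes no longer passed.

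**Figure D1:**
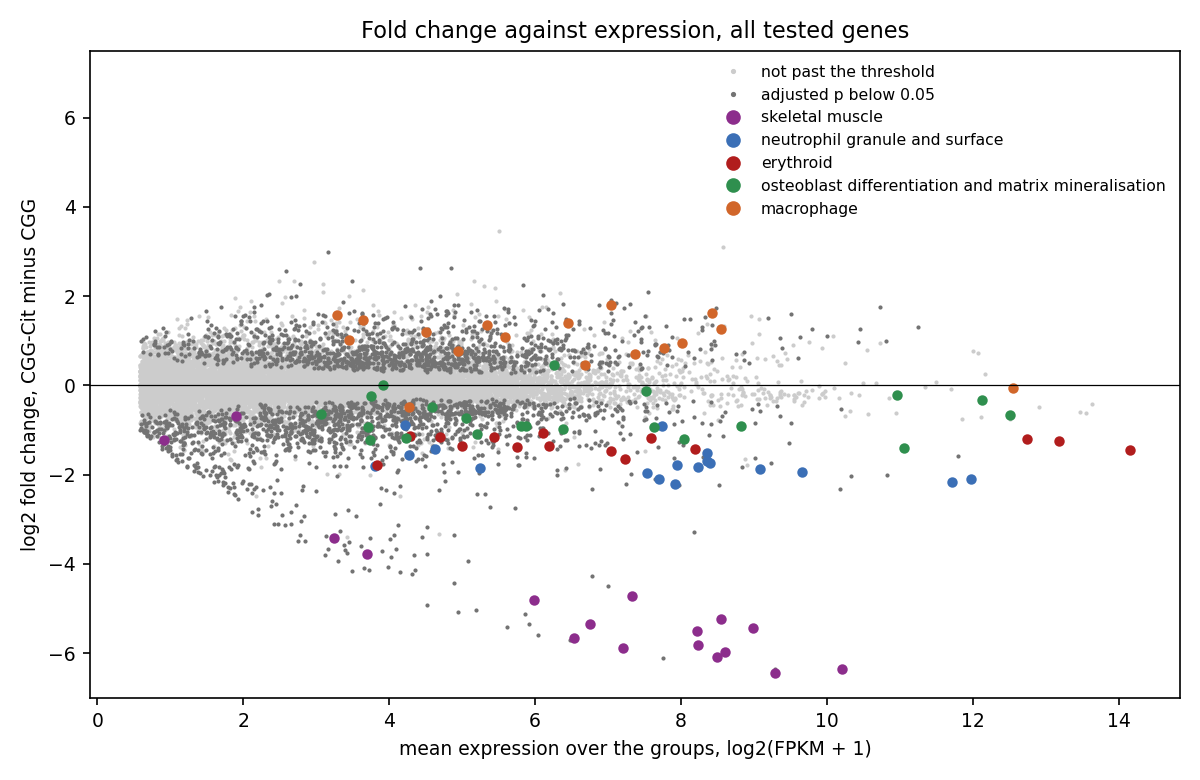
Log2 fold change (CGG-Cit minus CGG) of each of the 15965 tested genes against mean expression in log2(FPKM + 1), with the genes that passed in dark grey and members of 5 fixed lists in colour. The skeletal muscle genes (purple) reach -6.43, while 13 of the 17 macrophage genes (orange) passed as higher.

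Skeletal muscle genes showed the largest differences. Of 17 measured members of the list, 15 fell and 0 rose (17 adjusted over the list alone), with a median log2 fold change of -5.43. The 10 largest falls among named genes were Ckm, Acta1, Tnnc2, Myl1, Tnni2, Mb, Myoz1, Myh1, Cox6a2 and Pvalb, all expressed in muscle fibres, at log2 fold changes of -6.43 to -5.51. Acta1, the actin of skeletal muscle (ENSRNOG00000017786, listed at chromosome 19, 56674074 to 56677084), fell by 6.36 ± 0.777 (SE) on the log2 scale, with an adjusted p of 0.00823. Tnnt3, a troponin of fast fibres, fell from 728.6 ± 14.65 to 19.87 ± 10.56 FPKM (SD, n = 3), 36.7-fold. Ckm and Acta1 passed in every alternative fit, whereas Mb, the oxygen carrier myoglobin, did not without CGG 2, CGG 3, CGG-Cit 1 or CGG-Cit 2 (adjusted p up to 0.0934) and Tnnc2, Myl1 and Pvalb did not without CGG 3 (up to 0.0524). Camera placed the list below the other genes (adjusted p = 4.36e-13, and adjusted p = 0.425 with an estimated correlation). The list score was 2.512, 2.209 and 2.551 in CGG 1, 2 and 3 and -2.644, -3.402 and -1.224 in CGG-Cit 1, 2 and 3.

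Genes of blood cells and their marrow precursors formed the next group. Among neutrophil granule and surface genes, 17 of 18 fell (18 adjusted over the list alone), with a median log2 fold change of -1.81 and a camera adjusted p of 1.38e-09 (adjusted p = 0.425 with an estimated correlation). S100a9 (ENSRNOG00000011483, listed at chromosome 2, 190097554 to 190100276) fell from 6405 ± 322.2 to 1622 ± 825.9 FPKM (SD, n = 3). Retnlg fell by 2.21 on the log2 scale, the antimicrobial peptide gene Camp fell by 1.87, and Mpo, the myeloperoxidase of primary granules, fell by 1.75 ± 0.421 (SE; adjusted p = 0.0358). S100a8 no longer passed without CGG 3 (adjusted p = 0.0566). S100a9 no longer passed without CGG 2, CGG 3, CGG-Cit 1 or CGG-Cit 2 (adjusted p up to 0.0666), nor did Mpo without any of these, without CGG 1 or without the filter on low values (adjusted p up to 0.118). Camp no longer passed without CGG 2, CGG 3 or CGG-Cit 1 (adjusted p up to 0.0668), nor Retnlg without any of these or CGG-Cit 2 (up to 0.053).

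Of 15 erythroid genes 14 fell (15 adjusted over the list alone; median -1.35; camera adjusted p = 1.29e-08, and adjusted p = 0.425 with an estimated correlation). Tspo2 fell by 1.77, the beta globin gene Hbb-b1 by 1.66, the haemoglobin chaperone gene Ahsp by 1.43 and Klf1, a transcription factor of red cell precursors, by 1.38. Of 11 megakaryocyte and platelet genes 10 fell, also when adjusted over the list alone (median -1.37; camera adjusted p = 6.2e-06, and adjusted p = 0.425 with an estimated correlation). Ppbp fell by 1.78 and Clec1b fell by 1.49. Of 16 B and plasma cell genes 7 fell (10 adjusted over the list alone; median -0.92; camera adjusted p = 9.34e-06, and adjusted p = 0.425 with an estimated correlation). These included Igll1, a part of the surrogate light chain of B cell precursors, at -1.81, Vpreb3 at -1.40 and Cd79b at -1.33. All 21 measured cell cycle genes fell, also over the list alone (median -1.08; camera adjusted p = 1.46e-10, and adjusted p = 0.425 with an estimated correlation). Ccnb1 stood at -1.14, Cdk1 at -1.13, Aurkb at -1.13 and Pcna at -0.73. Tspo2 passed in every alternative fit, whereas Hbb-b1, Ahsp, Vpreb3 and Ccnb1 did not without CGG 3 (adjusted p up to 0.0583) and the other genes named here did not without CGG 3 and 1 to 4 other libraries (up to 0.0924). In the muscle, neutrophil, erythroid, platelet and cell cycle lists CGG-Cit 3 had the highest score of the CGG-Cit libraries and CGG-Cit 2 the lowest, whereas in the B and plasma cell list CGG-Cit 1 was lowest (-0.654, -0.434 and -0.222 in CGG-Cit 1, 2 and 3). After rescaling to TPM, 4 B and plasma cell genes fell.

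**Figure D2:**
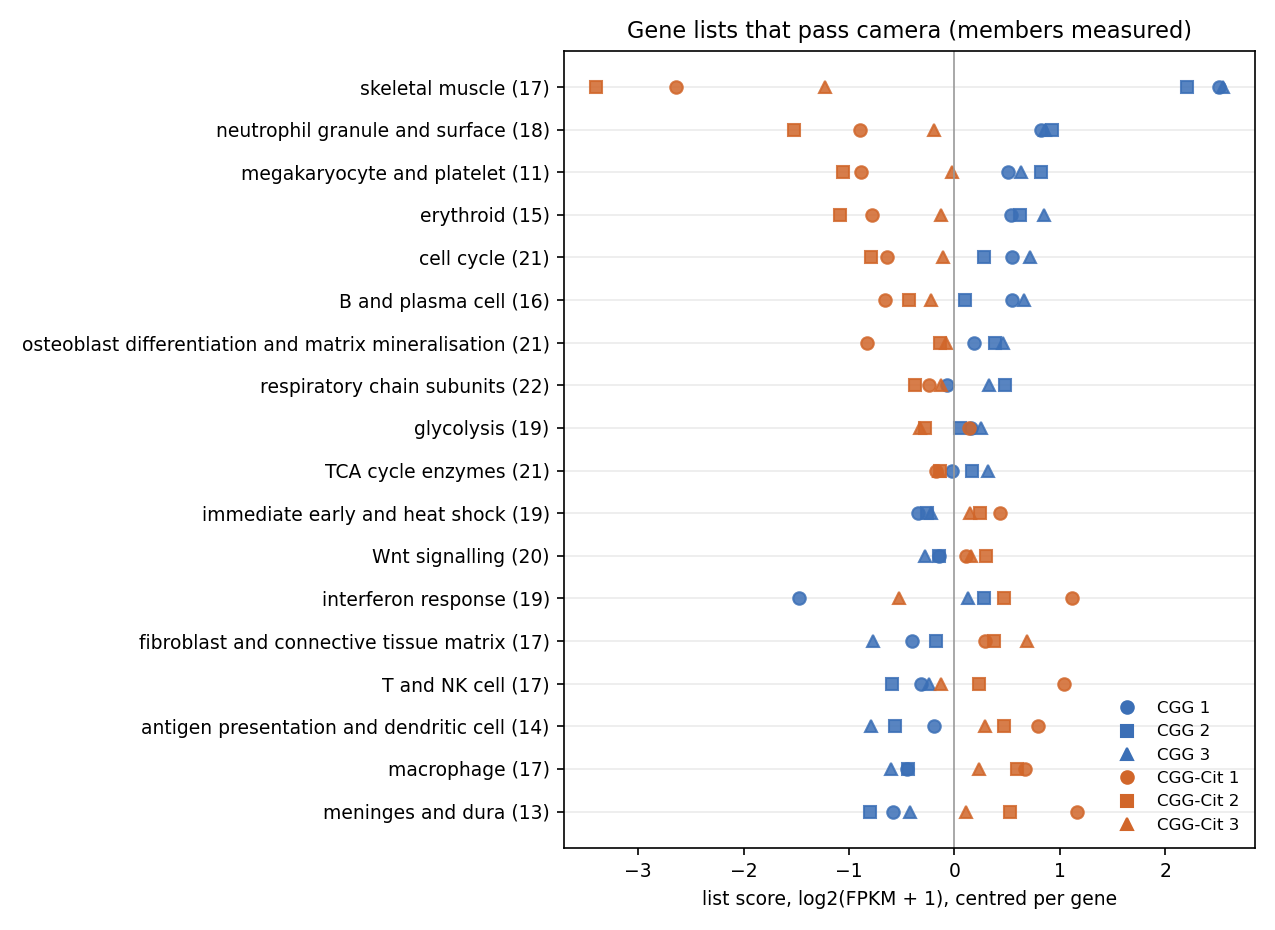
Score of each library (blue CGG, orange CGG-Cit, symbols for replicates) for the 18 lists that passed camera, as the mean over members of log2(FPKM + 1) centred per gene, with the number of measured members in parentheses. The groups lie apart by most in skeletal muscle, where the lowest CGG score is 2.209 and the highest CGG-Cit score -1.224, and they overlap in the interferon response, where CGG 1 lies at -1.474, and in glycolysis, where CGG-Cit 1 lies at 0.142.

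Of 21 measured osteoblast genes 7 fell and 0 rose in CGG-Cit (11 adjusted over the list alone), with a median log2 fold change of -0.91 and a camera adjusted p of 3.94e-05 (adjusted p = 0.585 with an estimated correlation, and 0.0886 with fry). Over the 18 alternative fits this median ranged from -0.93 to -0.536. Bglap (ENSRNOG00000019607, listed at chromosome 2, 187741770 to 187742747) fell by 1.40 ± 0.375 (SE; adjusted p = 0.0478). Ibsp, the bone sialoprotein gene, fell by 1.2 and Sp7, the osteoblast transcription factor osterix, fell by 1.17 ± 0.309. Alpl, the alkaline phosphatase of mineralising cells, fell by 0.97 and the collagenase gene Mmp13 fell by 0.94. Phospho1, a phosphatase of matrix vesicles, fell from 71.84 ± 7.527 to 37.73 ± 1.096 FPKM (SD, n = 3) and passed in every alternative fit. Runx2, the early osteoblast factor, averaged 13.59 ± 1.37 and 11.48 ± 1.66 FPKM (adjusted p = 0.263), Col1a1 7111 ± 1618 and 4515 ± 985.5 (adjusted p = 0.138) and Spp1 2036 ± 238.3 and 1957 ± 984.9 (adjusted p = 0.754). The score of the list was -0.826 in CGG-Cit 1, -0.139 in CGG-Cit 2 and -0.076 in CGG-Cit 3, against 0.189 to 0.463 in CGG. The skeletal muscle and neutrophil lists, with medians of -5.43 and -1.81, also scored lower in these 3 libraries. Bglap, Ibsp, Sp7 and Alpl no longer passed without CGG 1, CGG 2, CGG 3 or CGG-Cit 2, with adjusted p up to 0.146, 0.102, 0.14 and 0.0953, and Mmp13 without CGG 3, CGG-Cit 1 or CGG-Cit 2 (up to 0.0693). After rescaling to TPM and to equal totals without the 50 most abundant genes, Bglap (adjusted p = 0.0541 and 0.0532) and Sp7 (0.0552 and 0.0504) did not pass either, nor did Bglap with quantile normalization (0.0772), and without the filter on low values Bglap, Ibsp and Sp7 did not.

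Of 10 osteocyte genes 0 passed with limma over all genes (5 at an unadjusted p under 0.05 and 3 with voom). When adjusted over the list alone, Cd44 was higher (0.52) and Irx5 (-0.59) and Mepe (-0.95) lower, 1 and 2 genes (median -0.54; camera adjusted p = 0.431), while Dmp1 stood at -1.16 without passing. Over all genes Cd44 (adjusted p = 0.0502) passed in 9 of 18 alternative fits, among them the 4 other scalings, Irx5 in 3 and Mepe and Dmp1 in 1 each. Of 15 osteoclast genes Clcn7 (0.88), Tcirg1 (0.74) and Ocstamp (1.28) rose, and Car2 (-1.27) and Mmp9 (-0.92) fell (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.93). Mmp9 is also a member of the neutrophil list. Of 10 chondrocyte genes Sox6 fell by 0.72 (3 lower adjusted over the list alone; camera adjusted p = 0.179, and 0.0491 after rescaling to TPM). Of 19 mesenchymal stromal genes Pdgfra (0.73), Prrx1 (0.70) and Nt5e (0.74) rose and Cxcl12, the ligand that holds and draws marrow cells, fell by 0.77 (3 higher and 2 lower adjusted over the list alone; median 0.01; camera adjusted p = 0.524). Cxcl12 averaged 129.5 ± 15.08 FPKM in CGG and 76.77 ± 17.96 in CGG-Cit (SD, n = 3). Cxcl12 did not pass after rescaling to TPM (adjusted p = 0.0641), nor when any library but CGG-Cit 3 was left out (adjusted p up to 0.102). The calls of the other osteoclast, chondrocyte and stromal genes fixed by the naming rule also ended without CGG 3 (adjusted p up to 0.116), without CGG-Cit 2 (up to 0.132) and without 1 to 3 other libraries, while Pdgfra passed in every alternative fit. Mmp9 did not pass under TPM, quantile or equal-total scaling (0.0509 to 0.0592), nor without CGG 1, CGG 2, CGG 3 or CGG-Cit 2 (up to 0.115), and Sox6 did not under TPM (0.0795) or equal-total scaling (0.0509).

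Macrophage genes were higher in CGG-Cit. Of 17 measured members 13 rose and 0 fell (14 adjusted over the list alone; median 1.09; camera adjusted p = 5.46e-07, and adjusted p = 0.425 with an estimated correlation). Lgmn, a lysosomal protease, rose from 163.3 ± 9.899 to 521.2 ± 160.9 FPKM (SD, n = 3), the Fc receptor gene Fcgr3a by 1.79 on the log2 scale, the scavenger receptor gene Msr1 by 1.46 and Cd68 by 1.25. Of 14 genes of antigen presentation and dendritic cells 7 rose (11 adjusted over the list alone; median 0.99; camera adjusted p = 6.2e-06, and adjusted p = 0.425 with an estimated correlation). These included Ccr7 at 2.34, RT1-Da at 1.23, Cd74 at 1.1 and Itgax at 0.95. Msr1 passed in every alternative fit, Lgmn did not without CGG 3 or CGG-Cit 2 (adjusted p up to 0.0535), and Cd68 did not without CGG 3, CGG-Cit 1 or CGG-Cit 2 (up to 0.0656). Fcgr3a, Ccr7, RT1-Da, Cd74 and Itgax did not without CGG 3 or CGG-Cit 2 (up to 0.0962), nor, Itgax aside, without CGG 2 and 1 or 2 other libraries (up to 0.0788), and Ccr7 also not with voom (0.0658).

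In the list of T and NK cells, camera gave a shift upward (median 0.84; adjusted p = 0.000611, and adjusted p = 0.59 with an estimated correlation). The score was 1.036, 0.238 and -0.124 in CGG-Cit 1, 2 and 3, against -0.593 to -0.238 in CGG. Over the alternative fits the lowest median was 0.545. Of the 17 members of the list Cd28 alone rose (1.11) and Nkg7 alone fell (-1.40), and 10 were higher and 1 lower when adjusted over the list alone. After rescaling to TPM 7 rose and 1 fell, and fry gave an adjusted p of 0.148. Of 13 neutrophil chemoattractants and inflammatory cytokines, Ccl3 rose by 1.70 ± 0.163 (SE), and Fpr1 (-1.94), a receptor on neutrophils, and Ppbp (-1.78), a platelet chemokine, fell (also 1 and 2 adjusted over the list alone; camera adjusted p = 0.459). Cxcl1, a neutrophil attractant, averaged 0.622 ± 0.107 FPKM in CGG and 1.06 ± 0.615 in CGG-Cit (adjusted p = 0.395). Of 19 interferon response genes 0 passed with limma, also when adjusted over the list alone (4 at an unadjusted p under 0.05 and 0 with voom; median 0.81; camera adjusted p = 0.0203, and adjusted p = 0.705 with an estimated correlation). That camera call ended without CGG 1 (adjusted p = 0.322, median 0.37) and without CGG-Cit 1 (0.189, median 0.411), the libraries with the lowest and the highest score, and after rescaling to TPM (0.0609), where 2 genes rose, against 1 with quantile normalization. Ccl3 passed in every alternative fit, and Cd28, Nkg7, Fpr1 and Ppbp did not without CGG 2, CGG 3 or CGG-Cit 1 (adjusted p up to 0.0921) or without 1 or 2 other libraries (up to 0.0798).

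Fibroblast and connective tissue matrix genes rose in 8 of 17 cases and fell in 0 (13 higher adjusted over the list alone; median 0.84; camera adjusted p = 6.2e-06, and adjusted p = 0.425 with an estimated correlation). Mfap5, a microfibril protein, rose by 1.55, the fibril-associated collagen gene Col14a1 by 1.52, the fibrillin gene Fbn1 by 1.18 and the collagen cross-linking enzyme gene Lox by 0.50. Of 13 genes of meninges and dura Igfbp2 (2.63) and Slc13a4 (2.03) rose (6 adjusted over the list alone; median 1.10; camera adjusted p = 0.00153, and adjusted p = 0.425 with an estimated correlation). The 10 largest rises among named genes were Igfbp2, Cldn11, Ccl19, Ccr7, Stmn2, C4b, Sfrp2, Nfs1, Slc13a4 and Ccl9, at 2.63 to 2.03. Sfrp2, a secreted modulator of Wnt signals (ENSRNOG00000009465, listed at chromosome 2, 182723854 to 182731764), rose from 71.01 ± 21.74 to 300.9 ± 52.02 FPKM (SD, n = 3), with an adjusted p of 0.00591. It passed in every alternative fit, as did C4b and Nfs1. After rescaling to TPM, 13 connective tissue and 5 meningeal genes rose. The meningeal list did not pass fry (adjusted p = 0.0536). Igfbp2 did not pass without CGG 1, CGG 2, CGG-Cit 1 or CGG-Cit 2 (adjusted p up to 0.079). Ccr7, Cldn11 and Slc13a4 did not without CGG 1, CGG 2, CGG 3 or CGG-Cit 2 (up to 0.11), Cldn11 did not without CGG-Cit 1 (0.0946) and Slc13a4 did not with voom (0.0642). Ccl19, Ccl9 and Fbn1 did not without CGG 3 (up to 0.0609), and Mfap5, Lox and Stmn2 did not without CGG-Cit 2 (up to 0.0645), nor did Mfap5 without CGG 2 or CGG-Cit 1 and Lox without CGG 3 (up to 0.0533).

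Of 20 Wnt signalling genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.44; camera adjusted p = 0.0341, and adjusted p = 0.425 with an estimated correlation). Those that rose included Sfrp2 and Sfrp4 (1.27), secreted proteins that bind Wnt ligands, and the receptor genes Fzd1 (1.0) and Fzd2 (0.95), while Lef1, a transcription factor of the pathway, stood at -0.56 (adjusted p = 0.0498). Lef1 passed under none of the 4 other scalings (0.0502 to 0.15), nor when any library but CGG 2 was left out (up to 0.151). The camera call of this list was lost without CGG-Cit 2 (adjusted p = 0.0877), without the filter on low values (0.0725) and after rescaling to TPM (0.0909). Of 24 BMP and TGF-beta genes Bmp6 (1.46), Tgfbr2 (0.86), Tgfbr1 (0.76) and Bmpr2 (0.59) rose (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.206). Of 19 immediate early and heat shock genes 8 rose, also over the list alone (median 0.39; camera adjusted p = 0.000904, and adjusted p = 0.425 with an estimated correlation). Among them were Atf3 at 1.81, Fos at 1.54, Jun at 0.96 and Dusp1 at 0.9. Tgfbr2, Atf3 and Jun passed in every alternative fit, while Sfrp4, Fzd1, Fzd2, Bmp6, Tgfbr1, Bmpr2 and Fos did not without CGG 2 or CGG-Cit 2 (adjusted p up to 0.132). The first 6 of these also did not without CGG 3 and up to 3 other libraries (up to 0.125), Tgfbr1 not with quantile normalization (0.055) and Dusp1 not without CGG 3 or CGG-Cit 2 (up to 0.0551).

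The lists of vessel, fat, nerve and skin genes did not pass camera. Of 14 endothelial genes 0 passed with limma, also when adjusted over the list alone (1 at an unadjusted p under 0.05, 0 with voom and 1 after rescaling to TPM; median 0.31; camera adjusted p = 0.121). Of 15 angiogenic factors Hgf rose by 0.73, also over the list alone (camera adjusted p = 0.121), and Vegfa averaged 13.93 ± 3.938 and 8.263 ± 0.297 FPKM (SD, n = 3; adjusted p = 0.0661, and 0.0295 without CGG 1). Of 12 genes of smooth muscle and pericytes only Des fell (-2.31), a filament gene that skeletal muscle also expresses, also over the list alone (camera adjusted p = 0.699). Of 14 adipocyte genes Fabp4 (1.52), Lpl (1.56) and Pparg (0.87) rose, the first 2 of which macrophages also express, and Slc2a4 (-2.29), a glucose carrier of muscle and fat, fell (4 and 1 adjusted over the list alone; median 0.96; camera adjusted p = 0.0686). The adipocyte list passed camera without CGG-Cit 1 (adjusted p = 1.66e-05), the library with its lowest score, and with sample quality weights (0.0117). The endothelial, angiogenic and smooth muscle lists passed camera without CGG 2 (0.0037, 0.0459 and 0.0295), and the first 2 of these also without CGG-Cit 1 (0.0131 and 0.0311). Of 10 genes of brain and nerve Stmn2 rose by 2.28 and Aqp4 fell by 2.0, also over the list alone (camera adjusted p = 0.516). Of 5 skin epithelium genes Krt79 fell by 1.5 (2 lower adjusted over the list alone; camera adjusted p = 0.313). Des and Slc2a4 passed in every alternative fit, and Hgf, Fabp4, Lpl, Pparg, Stmn2, Aqp4 and Krt79 did not without CGG-Cit 2 (adjusted p up to 0.0932). Hgf, Fabp4, Lpl and Krt79 also did not without CGG 1, CGG 2 or CGG 3, Hgf and Krt79 not without CGG-Cit 1, Fabp4 and Lpl not without CGG-Cit 3 and Aqp4 not without CGG 3 (up to 0.103).

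Of 22 respiratory chain subunits 15 fell (20 adjusted over the list alone; median -0.56; camera adjusted p = 2.6e-08, and adjusted p = 0.425 with an estimated correlation). These included Cox5a at -0.72 and Ndufa4 at -0.70. Of 21 TCA cycle enzymes 7 fell, also over the list alone (median -0.27; camera adjusted p = 0.000348, adjusted p = 0.59 with an estimated correlation, and 0.0934 with fry). Mdh2 stood at -0.67, Pdhb at -0.65, Fh at -0.56 and Idh3g at -0.52. After rescaling to TPM 9 respiratory chain genes and 3 TCA cycle genes fell, with medians of -0.39 and -0.10. Of 19 glycolysis genes 5 fell and the glucose carrier gene Slc2a1 rose by 1.69 (7 lower and 1 higher adjusted over the list alone; median -0.35; camera adjusted p = 0.0492, and adjusted p = 0.705 with an estimated correlation). The largest falls were those of Pfkm (-2.71), the muscle form of phosphofructokinase, Aldoa (-1.28), the aldolase of muscle, and Pfkfb4 (-1.07). The glycolysis call ended without CGG 1, CGG 3, CGG-Cit 2 or CGG-Cit 3 (adjusted p up to 0.291) and under median-of-ratios (0.0507) and quantile scaling (0.0534) and the higher filter (0.0603). Without CGG-Cit 3 the glycolysis median was -0.159. Slc2a1 and Pfkfb4 did not pass without CGG 1, CGG 3, CGG-Cit 1 or CGG-Cit 2, nor Slc2a1 without CGG 2 (up to 0.12). Pfkm and Aldoa passed in every alternative fit, and Cox5a, Ndufa4, Mdh2, Pdhb, Fh and Idh3g did not without CGG 2, CGG 3 or CGG-Cit 2 (up to 0.0867). All 6 but Cox5a also did not without CGG-Cit 1 (up to 0.0662), Fh not without CGG 1 (0.0556), and Fh and Idh3g not after rescaling to TPM (0.0766 and 0.069). The skeletal muscle score was also lower in all 3 CGG-Cit libraries (-3.402 to -1.224), whereas the glycolysis score of CGG-Cit 1, 0.142, lay within the 0.055 to 0.249 of CGG. The respiratory chain score was -0.069, 0.479 and 0.329 in CGG 1, 2 and 3, against -0.374 to -0.123 in CGG-Cit. The TCA cycle score was -0.023, 0.168 and 0.317, against -0.176 to -0.137. CGG 1 thus lay nearest to CGG-Cit in both lists, but not in the score of the muscle list, where it stood at 2.512. Single muscle genes ordered the CGG libraries differently. Mb stood at 94.61, 881.8 and 792.7 FPKM in CGG 1, 2 and 3 and Cox6a2 at 83.66, 153.7 and 147, whereas Pvalb stood at 1057, 292.2 and 395.7. The muscle score therefore does not settle whether muscle content bears on these falls.

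Among 15 genes of citrate transport and acetyl-CoA supply, Slc13a5, Acacb, Me1 and Acss1 fell and Aco1 and Idh1 rose (6 lower and 3 higher adjusted over the list alone; median -0.11; camera adjusted p = 0.356). Slc13a5, which carries citrate into cells (ENSRNOG00000014870, listed at chromosome 10, 58810058 to 58834538), fell from 10.55 ± 4.851 to 3.252 ± 1.814 FPKM (SD, n = 3), a log2 fold change of -1.45 ± 0.378 (SE; adjusted p = 0.0441). It did not pass when any library but CGG-Cit 3 was left out (adjusted p up to 0.133). Me1, the cytosolic malic enzyme, fell by 0.86 and passed in every alternative fit, whereas Idh1 did not when any library but CGG 2 was left out (adjusted p up to 0.102). Acss1 did not when any library but CGG-Cit 3 was left out (adjusted p up to 0.0802), Aco1 not without CGG 1, CGG 2, CGG 3 or CGG-Cit 2 (up to 0.0802) and Acacb not without CGG 3 or CGG-Cit 2 (up to 0.0593). Slc25a1, the mitochondrial citrate carrier, averaged 14.23 ± 1.419 and 14.09 ± 2.527 FPKM (adjusted p = 0.924), and Acly, which makes acetyl-CoA from citrate, 31.45 ± 3.525 and 27.67 ± 2.746 (adjusted p = 0.318). Of 15 histone acetyltransferase genes Hat1 fell by 0.63, also over the list alone (median -0.02; camera adjusted p = 0.699), and Kat2a averaged 12.37 ± 0.23 and 12.32 ± 0.431 FPKM (adjusted p = 0.967). Of 16 histone deacetylase and sirtuin genes Hdac1 fell by 0.44, and 0 passed with limma when adjusted over the list alone (3 at an unadjusted p under 0.05 and 1 with voom; median -0.06; camera adjusted p = 0.475). Hat1 and Hdac1 did not pass after rescaling to TPM (adjusted p = 0.0688 and 0.189), nor when any library but CGG-Cit 3 was left out (adjusted p up to 0.0819 and 0.102). The medians of the citrate, acetyltransferase and deacetylase lists turned to 0.05, 0.14 and 0.11 after rescaling to TPM.

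**Figure D3:**
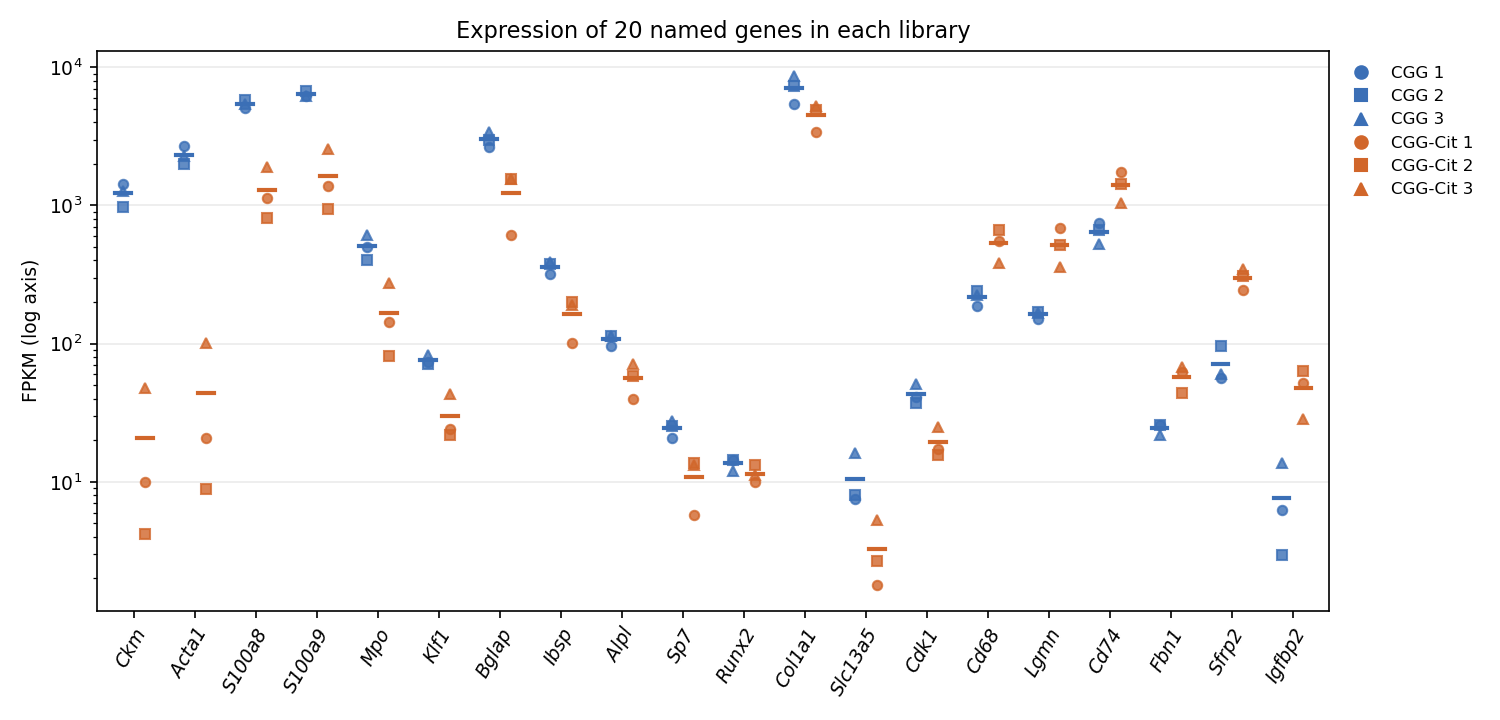
FPKM on a log axis of 20 named genes in each library (blue CGG, orange CGG-Cit, symbols for replicates), with a bar at each group's mean of 3 libraries. Ckm averages 1231 FPKM in CGG and 20.62 in CGG-Cit, Sfrp2 71.01 and 300.9, and the libraries of the groups overlap for Runx2.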

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

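The alternatives were fixed before the data were examined, except the voom fit on recovered whole reads, which gave 1345 genes higher and 1590 lower, 2606 of them also called on log2(FPKM + 1). The counts of higher and lower genes, 1237 and 1561, stayed within 1.5 times under other pseudocounts, filters, median-of-ratios, quantile or trimmed-total scaling, robust variance and sample quality weights (842 to 1653 higher, 1133 to 2005 lower). Rescaling to TPM gave 2203 and 948, with the median of all genes moved to 0.16, and 2176 genes were called in both fits. A required log2 fold change of at least 1 gave 328 and 672 and an adjusted p under 0.1 gave 2083 and 2413, as those thresholds are narrower and wider. Leaving out 1 library gave 122 to 1312 higher and 190 to 1622 lower genes and 16 to 21 lists, with fewer samples in each fit. Of 18 lists that passed camera, 0 passed with an estimated correlation between genes, which lay as high as 0.934 for the interferon list against the preset 0.01, and 12 passed fry. Those that did not were the lists of meninges (adjusted p = 0.0536), osteoblasts (0.0886), TCA cycle (0.0934), glycolysis (0.0934), T and NK cells (0.148) and interferon response (0.46). The lists of glycolysis, Wnt signalling and interferon response lost their call in 7, 3 and 3 of 18 alternatives, and the other 15 kept it with the preset correlation. Same-numbered libraries did not deviate together (correlations of -0.096, 0.002 and -0.078). With 3 libraries per group these values cannot show whether libraries of the 2 groups share a rat. No label states this, and the replicate block follows a shared number only. It gave 612 genes higher and 1055 lower. Under it 20 calls of named genes were lost, whereas the adipocyte list (camera adjusted p = 0.0433) and Dmp1, Col11a1 and Col11a2 (limma, 0.0178 to 0.0284) passed. The block spends degrees of freedom of the fit on the replicate numbers, which by itself lowers power. Whether this alone gave the lower count was not tested. No library correlated best with its own number in the other group. Over the named genes and all alternatives 361 fits lost a call, 50 gained it and 2429 stayed on their side of the threshold, 12 uncalled values changed sign, and no called gene or list changed direction. For called genes this was fixed in advance when 1 library was left out, as their groups did not overlap. At 14744207 to 16224920 reads per library 1 read in a gene of 1 kb is worth 0.0596 to 0.0657 FPKM, which limits what can be said of genes under the filter of 0.5 FPKM, such as Cxcl2.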

Other observations

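The gene families grouped by name and the tests of explanations were chosen after the results were seen, so the families are no independent evidence, whereas the splits of the libraries, the fixed lists and the genes of the naming rule were planned. Of 13 cathepsin genes 7 rose in CGG-Cit, Ctsb from 809.9 ± 74.08 to 1991 ± 434 FPKM (SD, n = 3), Ctsl by 1.25, Ctss by 1.36 and Ctsd by 1.06 on the log2 scale. Ctsg, a neutrophil granule protease, and Ctse fell, Ctse not after rescaling to TPM (camera adjusted p = 0.0011, and adjusted p = 0.213 with an estimated correlation). Gpnmb, a lysosomal membrane protein of macrophages and osteoclasts, rose from 764 ± 135.7 to 2613 ± 737 FPKM. Of 25 chemokine genes Ccl19, Ccl3, Ccl9, Cxcl9, Cxcl13 and Cxcl16 rose and Cxcl12 fell, the latter not after rescaling to TPM (camera adjusted p = 0.000136, and adjusted p = 0.213 with an estimated correlation). Ccl19, a ligand of Ccr7, rose from 0.804 ± 0.818 to 9.17 ± 2.44 FPKM. Of 33 collagen genes 8 rose, among them the basement membrane genes Col4a1 (0.84) and Col4a2 (0.82) and Col8a1 (1.38), and Col22a1 fell by 1.43 (camera adjusted p = 0.0138, and adjusted p = 0.376 with an estimated correlation). After rescaling to TPM 14 collagen genes rose. Ctsl passed in every alternative fit, whereas the other cathepsin, chemokine and collagen genes named here and Gpnmb did not without CGG 3, except Ccl3 (adjusted p up to 0.125). Of these, all but Gpnmb, Ccl19, Ccl9 and Col8a1 also did not without 1 to 4 other libraries (up to 0.132). The bone collagen gene Col1a1 stood at -0.65 without passing.

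Cox6a2 and Cox8b, respiratory chain subunits of striated muscle, fell in CGG-Cit. Cox6a2 averaged 128.1 ± 38.64 and 2.09 ± 2.34 FPKM (SD, n = 3) and Cox8b 43.63 ± 21.93 and 0.38 ± 0.491. Cox6a1, expressed more widely, stood at a log2 fold change of 0.13 (adjusted p = 0.467) and Cox8a at 0.12 (adjusted p = 0.492). Rpl3l, a ribosomal protein of striated muscle, fell by 3.40, while Rpl3 stood at -0.22 (adjusted p = 0.152). Of 80 cytosolic ribosomal protein genes 6 fell and 1 rose, against 1 and 1 after rescaling to TPM. Mitochondrially encoded genes made up 16.34% of all FPKM in CGG 2 and 9.02% to 11.93% in the other libraries, and 0 of 13 passed with limma (6 at an unadjusted p under 0.05 and 0 with voom). Ptgds, an enzyme of the meninges, stood at 15.38 to 269.2 FPKM in CGG and 110.7 to 1540 FPKM in CGG-Cit and did not pass (adjusted p = 0.146).

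Splitting the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. Only 1 split, the real grouping, gave as many genes, 2798 against at most 1 in the others, and 1 split gave as many lists, 18 against at most 16. The other splits passed 6 to 16 lists at the preset correlation although 0 or 1 genes were called in them, so a small camera p is also reached under wrong groupings. Each of these splits mixes the 2 groups unevenly. Part of the difference between the groups thus remains in it, and part adds to the spread within each side. Their counts of lists and genes are therefore no measure of false calls.

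The fall of skeletal muscle genes in CGG-Cit is the largest pattern. Scaling between libraries does not account for it, as the list's median stayed at or below -5.34 under 4 other scalings. Less muscle in the trimmed pieces is a candidate explanation. Of the list's genes with a CGG mean of at least 10 FPKM, Acta1 aside, 100% of 14 put the 3 CGG-Cit libraries in the order of Acta1. Outside the list Myoz1 and Cox6a2 put CGG-Cit 1 below CGG-Cit 2, against Acta1, and proportions varied between CGG libraries, Mb from 94.61 to 881.8 FPKM. An effect of the gel on muscle at the defect edge could give the same order and stays open, as no label records how the pieces were trimmed, and no gene marks the gel, so that an exchange of the 2 groups' labels could not be tested.

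Neutrophil, erythroid, platelet and B and plasma cell lists were all lower, though CGG-Cit 2 had the lowest score in the first 3 and CGG-Cit 1 in the B and plasma cell list. Scaling does not account for it, since the median of each of these 4 lists stayed at or below -0.83 under 4 other scalings. Fewer mature neutrophils alone would leave the erythroid and platelet lists in place, whose medians were -1.35 and -1.37. Those falls are part of the pattern itself and were known when this test was chosen. The comparison thus restates the pattern and is no independent test. Less blood with marrow unchanged would leave marrow precursor genes in place, but 14 of 15 such genes of the fixed lists fell (median -1.52, range -1.97 to -0.79). These 15 genes were picked after their values were seen, from lists already found lower, so their fall does not exclude that explanation. Less bone marrow stays open, through marrow formed within the new bone or taken with the pieces, and the lower cell cycle genes may belong to the same precursors, which was not tested.

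Of 21 osteoblast genes 7 fell. Scaling does not account for the lower list, since the list's median stayed at or below -0.74 under 4 other scalings. Over all 18 alternative fits it came as near to 0 as -0.536. Less bone in the pieces would lower osteocyte genes as well, but the median of -0.54 of the fixed osteocyte list, with 0 of 10 passing with limma, 5 at an unadjusted p under 0.05, 3 with voom and 1, as higher, under each of 4 other scalings, does not decide it. Of its 4 members with the smallest p, Cd44 (0.52) stood higher and Dmp1 (-1.16), Mepe (-0.95) and Irx5 (-0.59) lower, none passing over all genes with limma on log2(FPKM + 1). With voom Cd44 passed as higher and Mepe and Irx5 as lower. Dmp1 passed as lower with the replicate block (limma, adjusted p = 0.0178). CGG-Cit 1 had the lowest osteoblast score and CGG-Cit 2 the lowest muscle and neutrophil scores, and an effect of the gel on osteoblasts stays open and untested.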
